A study of Mus musculus with 9 samples.

How the data were processed

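Argonaute (AGO) CLIP-seq recovers the RNA that ultraviolet light crosslinks to AGO, the protein that carries microRNAs to their targets. It was done on livers of 9 mice aged 6 weeks, 5 floxed littermate controls and 4 miR-122 knockouts (KO). Per the labels' protocols, frozen liver was powdered and crosslinked, lysates were treated with DNase and partially digested with RNase, AGO complexes were isolated with a pan-AGO antibody, and a second amplification added a 4 nt index. Group, replicate number and sex were taken from the labels, and each library came from a separate mouse per the labels. The controls were 3 females and 2 males, and the KO mice 1 female and 3 males.

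Per the submitters' processing notes, Bowtie2 and the genome build mm10 were used; versions, the peak caller, the treatment of duplicate reads and the counting rule are not given in the sources used here. The deposited matrix held 143524 rows, 1 per peak and seed match, for 92645 unique peaks with a median width of 70 bases. Values per library were read counts per peak, not normalized, per the file headers; they were whole numbers, and the counts of a peak were equal in each of its rows. The deposited log2 fold change was the authors' control over KO value, which equalled log2((control sum + 1)/(KO sum + 1)) plus a constant of 0.337. The deposited conservation score was the mean phyloP of the 6 bases of a seed match, per the file headers. Peaks, their annotation classes, gene names and the seed matches of 31 microRNA families were used as deposited. A seed match is a short run of bases complementary to the 5' end of a microRNA, and the classes 8mer, 7mer-m8, 7mer-A1 and 6mer run from the longest to the shortest match. What defines the additional class that the deposited names mark with "-B" is not given in the sources used here.

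Library totals over unique peaks ran from 445912 to 1170130 counts. A floor of 3 counts corresponded to 2.56 to 6.73 CPM (counts scaled to a common library total) in a single library, and to 0.713 CPM over the control group and 0.807 CPM over the KO group. The libraries were amplified and the treatment of duplicates is unknown, so intervals and floors cover counting error only. Folds against a group without any count are lower bounds against the floor over that group. No pair of replicates was alike within counting noise: chi-square per degree of freedom ran from 2.74 to 8.87. CPM are scaled by the library total, except where TMM scaling is named, and log2 fold changes come from the TMM-scaled model, KO over control. Gene names were the file's. Of 64157 exonic peaks, 99.2% lay within 1 kb of the named gene in a reference table on GRCm38, the build that mm10 denotes. Names of month form, 20 in all, were not used, and 11.0% of counts lay in peaks without a gene. Those peaks were kept in the test of regions and left out of the test of genes. The counting rule for strand, near-identical copies and overlapping genes is unknown, so such genes are named as uncertain.

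Regions were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr, glmQLFit and glmQLFTest with genotype and sex as terms, over all 9 libraries, with Benjamini-Hochberg adjustment at 0.05. Counts of 13770 genes, summed over the peaks of each gene, were tested in the same way. The filter keeps a row with enough reads in either group alone. A row with few or no reads in the other group was thus tested only because the groups differed, and its direction was fixed in advance. Every adjusted p given for a single region or gene is from edgeR's quasi-likelihood test unless another tool is named. An SE beside a log2 fold was derived from that test's statistic. It does not cover the counting error where a group held only a few reads. Sets of regions or genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the estimated correlation beside it and fry as an alternative. Shares of counts per library were compared by two-sided exact permutation over all splits of 5 and 4 libraries, whose smallest p is 0.00794, and over the 40 arrangements within sex, whose smallest p is 0.025. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9 were used for tables and plots. On simulated counts for the 17182 regions tested, the region test recovered 54% of regions with a true log2 fold of -2, 6% at -1, 32% at 1 and 98% at 2, with 2 false calls. For the 8843 genes tested, the recovered shares were 96%, 30%, 50% and 100%, with 1 false call. Each simulation changed 200 rows by these folds and shifted a set of 100 by -0.5. It held no change as wide as that between the real groups, so its rates may not carry over to these data. Across the 17182 regions, the authors' log2 value with its sign turned correlated with the fitted one at r = 0.997 (the authors' deposited table; regions are not independent replicates), and 83.0% had the same sign.

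Designs, alternatives, gene lists, microRNA families and the rule for named genes were chosen before the data were examined. The 19 lists were reported miR-122 targets, study candidates, hepatocyte products, sterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation, bile acid and drug metabolism, glycolysis, iron, cell cycle, fetal liver and tumour genes, stellate and matrix genes, Kupffer and immune genes, endothelial genes, bile duct genes, red cell genes, male-biased and female-biased liver genes, and the microRNA machinery. Members were taken from general knowledge and matched to current or older symbols. Of 18 families, 17 were matched to the file; the miR-221/222 family was not. The rule named, per test, the 8 genes with the largest fall and the 8 with the largest rise among those past the threshold, with no overlap between KO and control CPM and a mean of at least 5 CPM in the higher group (5 each way for sex). Among the rises, 1 gene that the rule gave in both tests is left out of the text. It further named the 10 genes with the smallest p among 3' UTR regions with a miR-122 7mer or 8mer, up to 4 members per list past the threshold (2 where none passed), up to 8 reported targets at region level, every measured study candidate, Y-linked genes and Xist, and the Mir122 locus. H19 and the microRNA genes other than Mir122 were chosen after their values were seen.

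The alternatives were DESeq2 1.42.0, limma-voom, other scalings (library size, upper quartile, TMM from rows without a miR-122 6mer match), no filter and a filter of at least 20 counts in at least 4 libraries, no sex or genotype term, the replicate number as a block, 3' UTR rows only, other seed definitions, set tests and permutations, and leaving out each library. After the data were seen, further alternatives were added: a neuron-marker score as a covariate, rows with a control mean of at least 1 CPM, male or control libraries only, and regions with no miR-122 site. Marker lists of neurons, oligodendrocytes, astrocytes, skeletal muscle, heart muscle, pancreas, kidney, lung and brain microRNA genes were also added then. Results were further compared with 100 splits of the libraries drawn at random. A wider window around each region needed a genome sequence, which was not used here.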

Results

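The study asked which RNAs AGO binds in mouse liver through miR-122, the most abundant microRNA of hepatocytes, by setting miR-122 KO livers against littermate controls. AGO-bound reads were counted over 92645 regions in 9 libraries, each from 1 mouse aged 6 weeks. The 5 control libraries held 709498, 445912, 1137064, 1170130 and 744936 counts, and the 4 KO libraries 1006450, 1026098, 1070610 and 612479. Controls 1 to 3 and KO replicate 1 were female, the others male.

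The region over Mir122 itself (mm10, chromosome 18, 65248844 to 65248982, annotated as a microRNA) held 447, 270, 378, 396 and 324 counts in the controls and 52, 3, 39 and 16 in the KO libraries. The TMM-scaled level was 494 ± 150 CPM in controls (SD, n = 5) and 27.2 ± 17.7 CPM in KO (n = 4), 18.2-fold lower (exact permutation p = 0.00794, two-sided, the smallest that splits of 5 and 4 libraries can give). All KO libraries lay below all controls, and none of them was free of reads at the locus. As a share of all deposited counts the levels were 468 and 29.3 CPM.

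**Figure D1:**
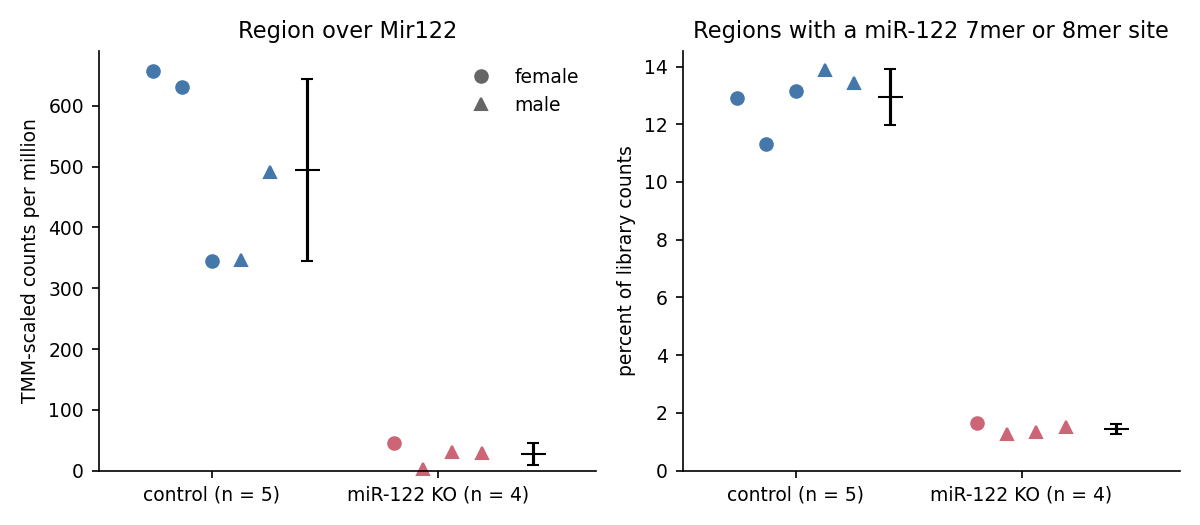
TMM-scaled CPM in the region over Mir122 and percent of library counts in regions with a miR-122 7mer or 8mer site, per library (circles female, triangles male), with mean and SD beside each group. The KO libraries lie below every control in both panels, with shares from 1.26 to 1.67% against 11.3 to 13.9%.

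AGO binding was lost across the regions that hold a miR-122 seed match. Regions with a 7mer or 8mer took 12.9% ± 0.976 of counts in controls (SD, n = 5) and 1.44% ± 0.179 in KO (n = 4), 8.96-fold less (two-sided exact permutation p = 0.00794; within sex, exact p = 0.025, the smallest possible). Of 1733 such regions tested, 1630 fell, 10 rose and 93 did not pass. Their median log2 fold change was -4.04, or -4.01 with the regions of an all-zero group set at their bound. The fall followed the length of the match, with medians of -4.68 for 461 regions with an 8mer (-4.49 at the bound), -3.92 for 570 with a 7mer-m8 and -3.82 for 702 with a 7mer-A1; of 904 regions with a 6mer, 739 fell and 24 rose. Regions without any miR-122 site, 13765 in all, had a median of 0.27, with 1753 lower and 2953 higher. Sites in coding sequence (672 regions, median -4.04) and in the 5' UTR (58 regions, -3.94) fell as well as those in the 3' UTR (505 regions, -3.51). The 181 regions in introns had a median of -5.03, or -4.58 at the bound. In the 3' UTR, the 136 regions with a conserved match (phyloP of at least 1) had a median of -3.39 and the 365 with a lower score -3.52, a difference that was not tested. By camera the set of 7mer and 8mer regions stood below the other regions (adjusted p = 1.7e-68 over 17 families; adjusted p = 0.0180 with an estimated correlation).

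**Figure D2:**
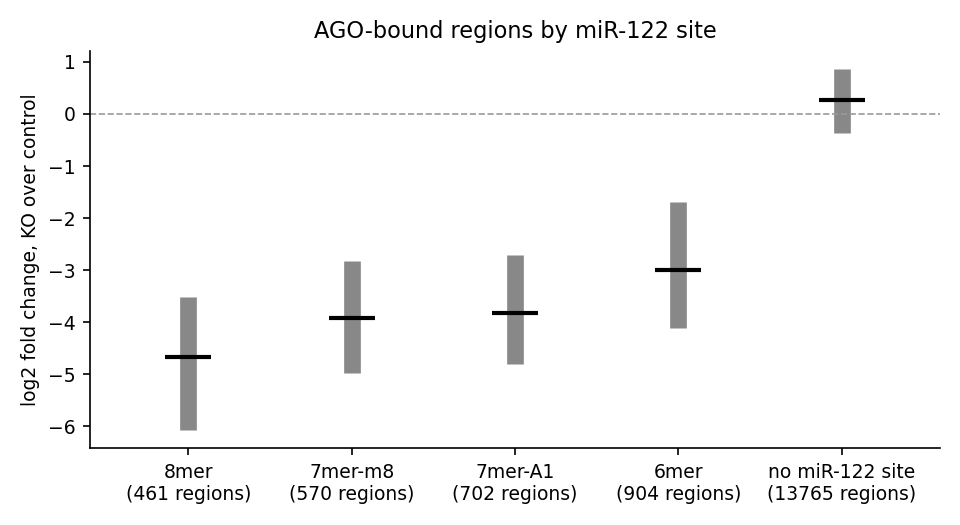
Fitted log2 fold change, KO over control, of AGO-bound regions by their miR-122 site; black lines are medians and grey bars run between the quartiles of the regions. Medians run from -4.68 for 8mer sites to 0.27 for regions without a site.

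Among 3' UTR sites, the smallest p-values belonged to regions well covered in the controls. The region in Rxra, a partner of many nuclear receptors (chromosome 2, 27760178 to 27760247), fell from 374 ± 38.2 to 4.34 ± 2.96 CPM (SD, n = 5 and 4; log2 -6.30, SE 0.38). That in Gata4, a transcription factor of liver development (chromosome 14, 63199835 to 63199904), fell from 132 ± 31.0 to 0.482 ± 0.557 CPM (log2 -7.82, SE 0.48), and that in Lgals3bp, a secreted glycoprotein, from 697 ± 118 to 18.1 ± 6.59 CPM (log2 -5.21). The Gata4 region held 2 reads over the KO group, under the group floor of 0.807 CPM, so the size of its fall is uncertain. The regions in 2900026A02Rik (log2 -5.40), the histone demethylase Kdm4a (-5.15), Hp1bp3 (-5.76), the procollagen proteinase Bmp1 (-5.74), the mitochondrial carrier Slc25a51 (-6.20) and Pacsin2 (-5.10) also fell. A region named Camta1 (chromosome 4, 151048831 to 151048900; log2 -4.72) lies over Vamp3 in the reference table, so its gene is uncertain. Of genes reported as miR-122 targets, Ccng1, a cyclin induced by p53 (chromosome 11, 40749041 to 40749110, 8mer in the 3' UTR), fell from 69.1 ± 14.04 to 4.87 ± 0.909 CPM (log2 -3.94, SE 0.34, adjusted p = 1.2e-07). The region of hemojuvelin, a co-receptor that controls hepcidin (Hfe2 in the file; chromosome 3, 96528826 to 96528895), fell from 121 ± 33.3 to 2.86 ± 3.32 CPM (log2 -5.41). Regions in Slc35a4 (-5.50), Ankrd13c (-5.49), Cux1 (-5.08), citrate synthase Cs (-4.11), Tmed3 (-3.40) and the transcytosis protein Mal2 (-3.28) fell too. With the neuron-marker score described for the rises as a covariate, an alternative added after the data were seen, the regions in Rxra, Gata4, Slc25a51, Slc35a4, Hfe2 and Ankrd13c were no longer past the threshold (adjusted p from 0.0505 to 0.620), at log2 values from -6.77 to -4.14. That score lay between 0.0180 and 0.0205 in every control and between 0.519 and 2.19 in KO, so it nearly coincided with genotype, and a call lost under it is no evidence against the fall.

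Across all regions the largest falls were at miR-122 sites and the largest rises at genes of nerve cells. In an LTR repeat within Galnt11 (chromosome 5, 25235879 to 25235948, 8mer) the level was 80.1 ± 65.6 CPM in controls (SD, n = 5), and no read was seen in KO (n = 4), at least 99.2-fold lower. An intronic 8mer region of the carboxylesterase Ces3a (chromosome 8, 105050358 to 105050427) fell from 199 ± 116 to 0.492 ± 0.568 CPM (log2 -8.63, SE 0.58, adjusted p = 1.7e-08). Its KO level is 2 reads, under the group floor of 0.807 CPM, so the size of this fall is uncertain. The 3' UTR region of Pfkfb2, a regulator of glycolysis (chromosome 1, 130696209 to 130696278), held 43.3 ± 4.98 CPM in controls and no KO read (at least 53.6-fold lower). Falls to no KO read were also seen in an LTR repeat in Rsrc1 (at least 86.1-fold), in Dscr3 (60.3-fold; Vps26c in the reference, overlapping Gm31323), in Pgls (57.1-fold; its only match is of the "-B" class), in Diap2 (53.2-fold; Diaph2 in the reference) and in Lta4h (50.9-fold). All 8 of these calls were lost with the neuron-marker covariate (adjusted p from 0.639 to 1), at log2 values from -9.37 to -4.69; the score nearly coincided with genotype, and 7 of the 8 had no KO read.

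Of the rises, the 3' UTR region of Aldoc, the aldolase of brain (chromosome 11, 78326448 to 78326517), had no control read and 114 ± 102 CPM in KO, at least 159.9-fold higher. Regions of Syn1, a synaptic vesicle protein (chromosome X, 20860895 to 20861026, 99.6 ± 85.0 CPM, at least 139.6-fold), the adhesion molecule Cadm2 (at least 137-fold) and Nap1l5 (123-fold; overlapping Herc3, with a miR-122 8mer match) likewise had no control read. So did 2 regions of uncertain name, Igsf5 (at least 146-fold), which lies over Pcp4 in the reference, and Epb4 (117-fold), which lies over Epb41l1. A region in the imprinted non-coding RNA Meg3 (chromosome 12, 109566236 to 109566305, overlapping Rtl1) rose from 0.879 ± 1.25 to 615 ± 482 CPM (log2 8.92, SE 0.69). In these 7 regions the level in KO replicate 4 was 3.08 to 4.21 times the mean of KO replicates 1 to 3. A set of 23 neuron markers chosen after the data were seen summed to 52.1 ± 2.89 CPM in controls and to 1426, 1590, 1970 and 6010 CPM in KO replicates 1 to 4, a ratio of 3.62 for replicate 4.

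In all, 7752 of 17182 regions passed, 4745 lower and 3007 higher (38.8% higher). Over all 17182, called or not, the KO and control CPM did not overlap in 6600 (38.4%), against 1.59% of equally likely splits. With upper quartile scaling the split was 4331 lower and 4219 higher (49.3% higher). With the neuron-marker score as a covariate, 4926 regions passed, 2558 lower and 2368 higher.

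Of 16 other microRNA families fixed for the liver, 14 stood higher than the remaining regions by camera, among them miR-26 (median log2 0.44; adjusted p = 0.000248), miR-21 (0.53; 21 and 69; adjusted p = 0.000248), miR-30 (0.33; 97 and 259; adjusted p = 0.000248) and let-7 (0.22; 146 and 243; adjusted p = 0.00622). The remaining regions included the 1733 with a miR-122 7mer or 8mer, at a median of -4.04, so a family can stand higher without a gain. Regions without a miR-122 site had a median of 0.27. With an estimated correlation none of the 16 passed (adjusted p from 0.0802 to 0.464 with an estimated correlation). The miR-24 (median 0.10, adjusted p = 0.375) and miR-148 family regions (with miR-152; median -0.33; 144 lower and 42 higher, adjusted p = 0.113) did not pass. Among regions without a miR-122 site, an alternative added after the data were seen, only the miR-148 family passed, lower, of the 16 (adjusted p = 7.4e-05; adjusted p = 0.351 with an estimated correlation). Of the file's families outside the fixed list, adjusted as a group of their own, miR-143-3p (median log2 0.70; 84 lower and 167 higher), miR-191-5p (0.69; 24 and 64), miR-126a-5p (0.47; 14 and 38) and miR-25/32/92a (0.48; 32 and 70) stood higher over all regions (adjusted p = 3.5e-05, 0.000593, 0.000911 and 0.000911; adjusted p from 0.165 to 0.247 with an estimated correlation). The first 3 also did among regions without a miR-122 site (adjusted p = 1.4e-05, 0.00405 and 0.00405; adjusted p = 0.374 with an estimated correlation for each). As shares of all counts, 7 of the 16 families were higher in KO by exact permutation. They included miR-21 (2.32% ± 0.579 against 3.66% ± 0.295; n = 5 and 4; exact p = 0.0159, adjusted p = 0.0337), miR-23 (2.01% against 2.68%; adjusted exact p = 0.0225) and the miR-148 family (2.92% against 3.98%; adjusted exact p = 0.0225). Without H19 regions the miR-148 family turned lower in KO (ratio 0.853; adjusted exact p = 0.0193).

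Coding sequence and 5' UTRs took smaller shares of AGO-bound reads in KO, and 3' UTRs and long non-coding RNAs larger ones. Coding regions took 38.3% ± 1.64 of counts in controls (SD, n = 5) and 27.0% ± 3.53 in KO (n = 4). Shares of 5' UTRs were 7.32% ± 0.469 and 4.53% ± 0.237, and those of 3' UTRs 28.2% ± 1.73 and 35.0% ± 1.09. Long non-coding RNA (lincRNA) rose from 1.11% ± 0.193 to 5.25% ± 0.547; without H19 these shares were 0.959% and 1.94%. Pseudogenes fell from 1.93% ± 0.106 to 1.36% ± 0.198, and LTR repeats from 1.73% ± 0.489 to 0.949% ± 0.0372. Shares of simple repeats (0.0277% and 0.0935%), of sequence downstream of genes (1.77% and 2.29%) and of the class the file calls other (1.10% and 1.51%) rose. In KO replicate 4 coding sequence was at 21.9% (27.9% to 29.9% in the other KO libraries) and simple repeats at 0.154% (0.0641% to 0.0820%). These 9 classes passed by two-sided exact permutation (adjusted p = 0.0215, and 0.0335 for LTR repeats and downstream sequence). Within sex none passed (adjusted exact p = 0.0594 at the lowest), nor with any 1 control left out, where 4 against 4 libraries allow no exact p below 0.0286.

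**Figure D3:**
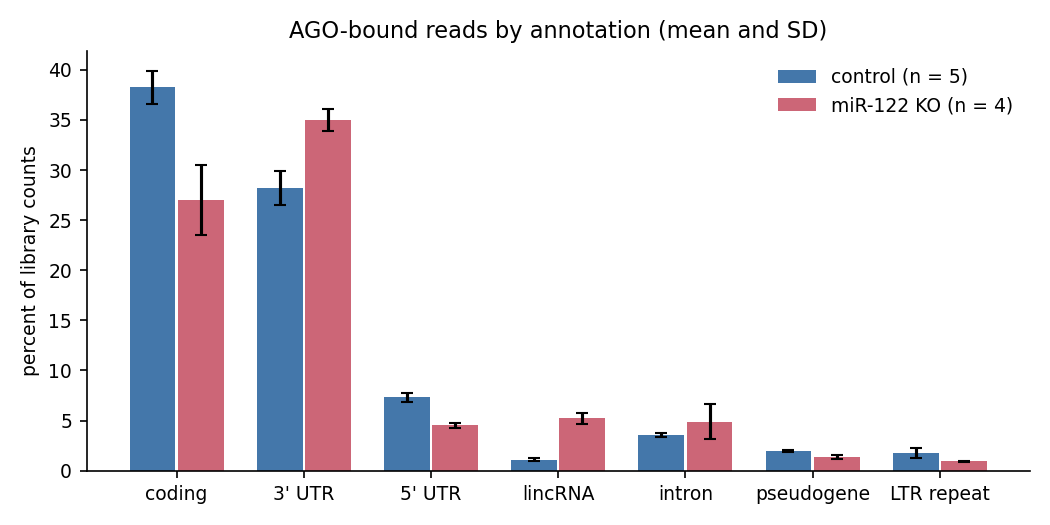
Percent of library counts by annotation class, mean with SD over 5 control and 4 KO libraries. Coding sequence fell from 38.3 to 27.0% and 3' UTRs rose from 28.2 to 35.0%.

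Summed over genes, AGO-bound reads fell to none or nearly none in several genes of 1 to 3 regions and rose from none in neuronal genes. Hscb, a co-chaperone of iron-sulfur cluster assembly, fell from 94.9 ± 23.9 to 0.492 ± 0.568 CPM (SD, n = 5 and 4; log2 -7.40, adjusted p = 2.8e-07). Its KO level is 2 reads, under the group floor of 0.807 CPM. Pgls, an enzyme of the pentose phosphate pathway (46.1 ± 18.6 CPM in controls, at least 57.1-fold lower), Rfx4 (at least 50.9-fold), the farnesyltransferase subunit Fntb (29.2-fold), the recombination protein Rad51b (26.8-fold), the mitochondrial tRNA enzyme Trmu (18.3-fold), Gm5561 (17.2-fold) and Gm12274 (15.2-fold) had no KO read. These 8 calls were lost with the neuron-marker covariate, which nearly coincided with genotype (adjusted p from 0.510 to 1), at log2 values from -8.29 for Pgls to -4.93 for Hscb. Pgls, Rfx4, Fntb, Hscb and Gm12274 had 1 region each, Rad51b and Trmu 2, and Gm5561 3. Such sums are therefore not separate evidence from the test of regions, and the Pgls value is that of its region given above. The splicing factor Rbfox1 had no control read and 527 ± 446 CPM in KO (at least 739-fold higher). Cadm2 (386-fold), Csmd1 (292-fold), the synaptic scaffold Dlgap1 (275-fold), the neuronal calcium sensor Vsnl1 (266-fold), Tmem178b (264-fold) and Slc24a2 (224-fold) were raised at least as much as given. In these 7 genes KO replicate 4 held 3.72 to 4.08 times the mean of the other KO libraries. Of 8843 genes 3996 passed, 2056 lower and 1940 higher (48.5% higher). Over all 8843, called or not, 3418 (38.7%) had no overlap of CPM, against 1.59% of equally likely splits. With TMM factors from rows without a miR-122 match, 2798 were lower and 1216 higher (30.3% higher).

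Genes of hepatocyte metabolism had less AGO-bound RNA in KO. Their sums include any regions with a miR-122 site, and the lists were not tested without those regions. Of 19 tested genes of bile acid and drug metabolism, 13 fell and 0 rose, with the same 13 and 0 when adjusted over the list alone. Cyp8b1, the sterol hydroxylase of cholic acid synthesis, fell from 2275 ± 681 to 88.7 ± 17.4 CPM (SD, n = 5 and 4; log2 -4.76). The transporters Slco1a1 (-3.17) and Slco1b2 (-1.46) fell, as did the bile salt export pump Abcb11 (-1.09), which did not pass over 3' UTR rows alone (-0.67, adjusted p = 0.0642). Of 16 genes of fatty acid and triglyceride synthesis 10 fell and 0 rose (10 and 0 adjusted over the list alone). Fatty acid synthase Fasn fell from 854 ± 147 to 157 ± 39.0 CPM (log2 -2.43), the desaturase Scd1 from 1511 ± 374 to 186 ± 29.99 CPM (-3.04), Acacb from 81.1 ± 33.9 to 8.98 ± 0.589 CPM (-3.47), and Acly was lower as well (-1.56). Of 15 genes of fatty acid oxidation 10 fell and 0 rose (11 and 0 adjusted over the list alone), with Hadhb (-1.24), Cpt2 (-1.23), Acadvl (-1.29) and the omega-hydroxylase Cyp4a10 (1062 ± 783 against 73.2 ± 33.6 CPM, -3.05; near copies exist). Of 17 genes of sterol synthesis 9 fell and 0 rose (10 and 0 adjusted over the list alone). Insig1, which holds back cholesterol synthesis, fell from 579 ± 158 to 154 ± 39.6 CPM (-1.89), as did squalene synthase Fdft1 (-1.62) and Sc4mol (-1.14; Msmo1 in current tables; adjusted p = 0.0824 with the neuron-marker covariate). Sc5d fell from 511 ± 62.8 to 182 ± 25.6 CPM (-1.57), but was at 0.14 over 3' UTR rows alone (adjusted p = 0.611). Of 24 hepatocyte products 15 fell and 2 rose (15 and 2 adjusted over the list alone). The urea cycle enzyme Arg1 fell from 1660.3 ± 154 to 149 ± 43.0 CPM (-3.48), though not past the threshold over 3' UTR rows alone (-0.25, adjusted p = 0.581). The plasma proteins Apoh (1135 ± 163 against 148.03 ± 35.2 CPM, -2.90), Apoc3 (-1.61) and Fgb (-1.56) fell. By camera these 5 lists passed (adjusted p = 0.000766 for bile acid and for fatty acid synthesis, 0.000898 for oxidation and hepatocyte products, 0.0142 for sterols), and each had adjusted p = 0.299 with an estimated correlation. Their sums were lower in KO replicate 4, the library with the most neuron-marker reads, than in the mean of the other KO libraries, at ratios of 0.605 for bile acid genes, 0.706 for fatty acid synthesis, 0.554 for oxidation, 0.759 for sterols and 0.757 for hepatocyte products.

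Matrix, macrophage and fetal genes had more. Of 14 stellate and matrix genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), among them the collagens Col1a1 (62.5 ± 15.3 against 249 ± 53.9 CPM, SD, n = 5 and 4; log2 1.82), Col3a1 (143 ± 27.5 against 530.5 ± 151 CPM, 1.65), Col1a2 (1.46) and Col5a2 (1.23). Of 15 Kupffer and immune genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), among them the macrophage receptor Csf1r (1.06), the antigen presentation genes H2-Aa (1.55) and Cd74 (1.14) and lysozyme Lyz2 (1.44). The fetal liver and tumour list held 14 genes, of which 10 had a region and 5 were tested. All 5 fetal liver and tumour genes tested rose (5 adjusted over the list alone). Sox4 and Meg3, with 17 and 20 control counts in all, passed the filter through the KO libraries, so the direction of these 2 was fixed in advance. Igf2, a fetal growth factor, rose from 74.8 ± 87.3 to 2464 ± 699 CPM (4.98), the transcription factor Sox4 from 3.55 ± 3.09 to 44.2 ± 16.2 CPM (3.28), Meg3 from 5.60 ± 6.32 to 3710.5 ± 3009.7 CPM (9.26) and Peg3 from 18.1 ± 9.41 to 251 ± 175 CPM (3.60). H19, the fifth member, chosen for its size after its values were seen, rose from 1537 ± 1735 to 33785 ± 4420.3 CPM (log2 4.34, SE 0.71, adjusted p = 0.000417). KO replicate 4 over the mean of the other KO libraries was 3.73 for Meg3 and 3.11 for Peg3, as for the neuron markers at 3.62, but 0.764 for Igf2, 0.559 for Sox4, 0.938 for H19, and 0.604 and 0.567 for the sums of the matrix and macrophage lists. By camera these 3 lists passed (adjusted p = 0.000766, 0.0154 and 0.000898; each adjusted p = 0.299 with an estimated correlation). The Kupffer list did not pass without KO replicate 1 (adjusted p = 0.0901), over 3' UTR rows alone (0.0903) or in male libraries alone (0.0901), nor did Lyz2 without KO replicate 1 (1.17, adjusted p = 0.0670) or in male libraries alone (1.12, adjusted p = 0.0937).

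**Figure D4:**
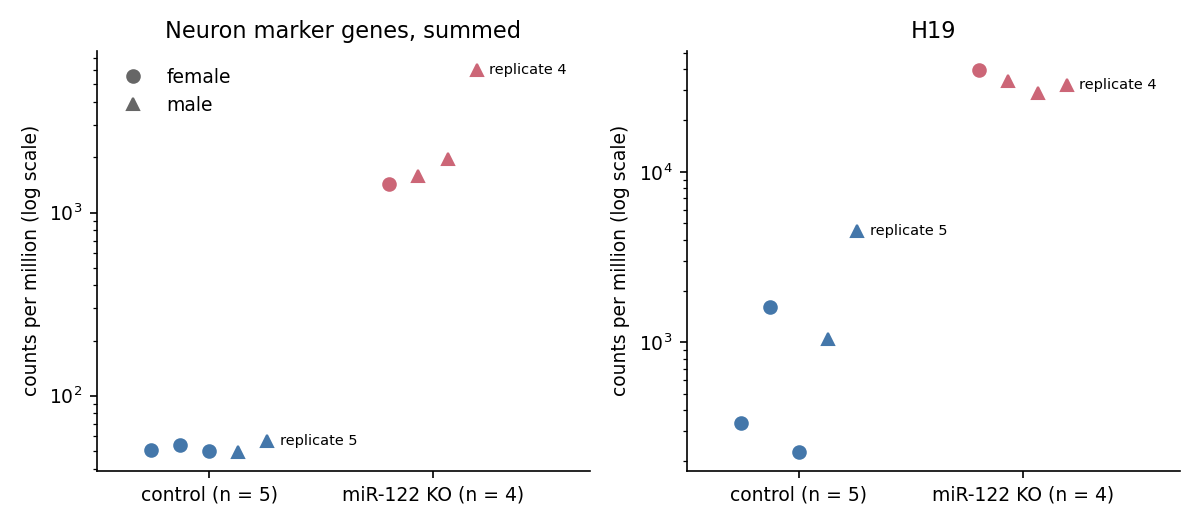
CPM, on a log scale, of 23 neuron markers summed and of H19 in each library (circles female, triangles male). Neuron markers reach 6010 in KO replicate 4 against 1426 to 1970 in the other KO libraries, while H19 lies between 29135 and 39643 in all 4.

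Lists named for other cell types differed among themselves, though powdered liver does not show which cells the reads came from. The bile duct list held 10 genes, of which 7 had a region and 4 were tested. Of 4 bile duct genes 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0536; adjusted p = 0.299 with an estimated correlation): osteopontin Spp1 (11.2 ± 5.34 against 79.9 ± 19.3 CPM, SD, n = 5 and 4; log2 2.67) and the keratins Krt8 (1.61) and Krt18 (1.23). As a list they passed by camera without control replicate 5 (adjusted p = 0.0285) and, in alternatives added after the data were seen, in male libraries alone (0.0345), among rows with a control mean of at least 1 CPM (0.0274) and with the neuron-marker covariate (0.0475), but not with an estimated correlation in any of these (adjusted p from 0.257 to 0.366 with an estimated correlation). Krt18 did not pass over 3' UTR rows alone (0.26, adjusted p = 0.637), nor Krt8 in male libraries alone (1.01, adjusted p = 0.0738). None of 12 endothelial genes passed by edgeR (0 adjusted over the list alone; camera adjusted p = 0.733), with Stab1 at -0.66 (adjusted p = 0.0566) and Stab2 at -0.45 (adjusted p = 0.149). Both passed with TMM factors from rows without a miR-122 match (adjusted p = 0.00842 and 0.0210), and Stab1 by limma-voom (adjusted p = 0.0435) and without the sex term (0.0398). None of 5 red cell genes passed either (0 adjusted over the list alone; camera adjusted p = 0.473), with the near-identical haemoglobin genes Hba-a2 at 0.54 (adjusted p = 0.148) and Hba-a1 at 0.52 (adjusted p = 0.151). With library size scaling they were past it (adjusted p = 0.0411 and 0.0418).

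Glycolysis, iron and growth genes went both ways. Of 14 glycolysis genes 7 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.157). Ldha fell from 629.6 ± 121.5 to 109 ± 31.9 CPM (SD, n = 5 and 4; log2 -2.44), and the liver pyruvate kinase Pklr (-2.36) and Gapdh (-3.71), which has many pseudogene copies, fell too. Platelet phosphofructokinase Pfkp rose from 5.53 ± 2.19 to 85.2 ± 46.0 CPM (3.69), with a replicate 4 ratio of 2.46. Of 14 iron genes 4 fell and 2 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.204): Hfe2 fell from 419 ± 73.6 to 45.5 ± 12.2 CPM (-3.30), Ireb2 (-1.49) and the zinc and iron carrier Slc39a14 (-0.91) fell, and Smad7 rose (0.97). The cell cycle list held 20 genes, of which 16 had a region and 5 were tested. Of 5 cell cycle genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.167). Myc rose from 7.43 ± 3.63 to 81.9 ± 59.9 CPM (2.92), Ccnd1 by 0.99 and Ccne2 by 0.89, and Pcna, the clamp of DNA replication, fell (-1.33). Ccne2 no longer passed without KO replicate 1 (0.68, adjusted p = 0.0574) or in male libraries alone (0.63, adjusted p = 0.146), nor did Smad7 in male libraries alone (0.91, adjusted p = 0.0611). In the microRNA machinery 1 of 12 genes fell and 1 rose (1 and 1 adjusted over the list alone; camera adjusted p = 0.779). Drosha, the nuclease that opens microRNA maturation, fell from 85.0 ± 12.7 to 7.22 ± 3.26 CPM (-3.65), and Ago2 rose from 136 ± 6.66 to 243 ± 24.1 CPM (0.77).

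Of 44 reported miR-122 targets 19 fell and 8 rose at gene level (19 and 8 adjusted over the list alone; camera adjusted p = 0.120; adjusted p = 0.421 with an estimated correlation). Over 3' UTR rows alone the list stood lower (camera adjusted p = 0.000196; adjusted p = 0.140 with an estimated correlation), as it did with the neuron-marker covariate, added after the data were seen (0.0375; adjusted p = 0.396 with an estimated correlation). Of the 4 study candidates 2 fell and 0 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.204). The study chose them on these samples, so the list is not independent evidence of its direction. Stx6, a vesicle fusion protein, fell from 45.9 ± 10.7 to 8.41 ± 2.10 CPM (SD, n = 5 and 4; log2 -2.58), and the riboflavin transporter Slc52a2 from 27.5 ± 9.35 to 10.1 ± 4.69 CPM (-1.45). Bcl9, a Wnt co-activator, was at -0.39 as a gene (adjusted p = 0.124; 0.0481 without control replicate 5, at -0.56; 0.0434 without the sex term and 0.0106 with TMM factors from rows without a miR-122 match), whereas a coding region of it with a match of the "-B" class (chromosome 3, 97207176 to 97207245) fell from 62.6 ± 21.3 to 1.12 ± 0.835 CPM (-5.52). Rabif was at 8.09 ± 4.35 and 18.4 ± 12.2 CPM (1.11, adjusted p = 0.165).

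**Figure D5:**
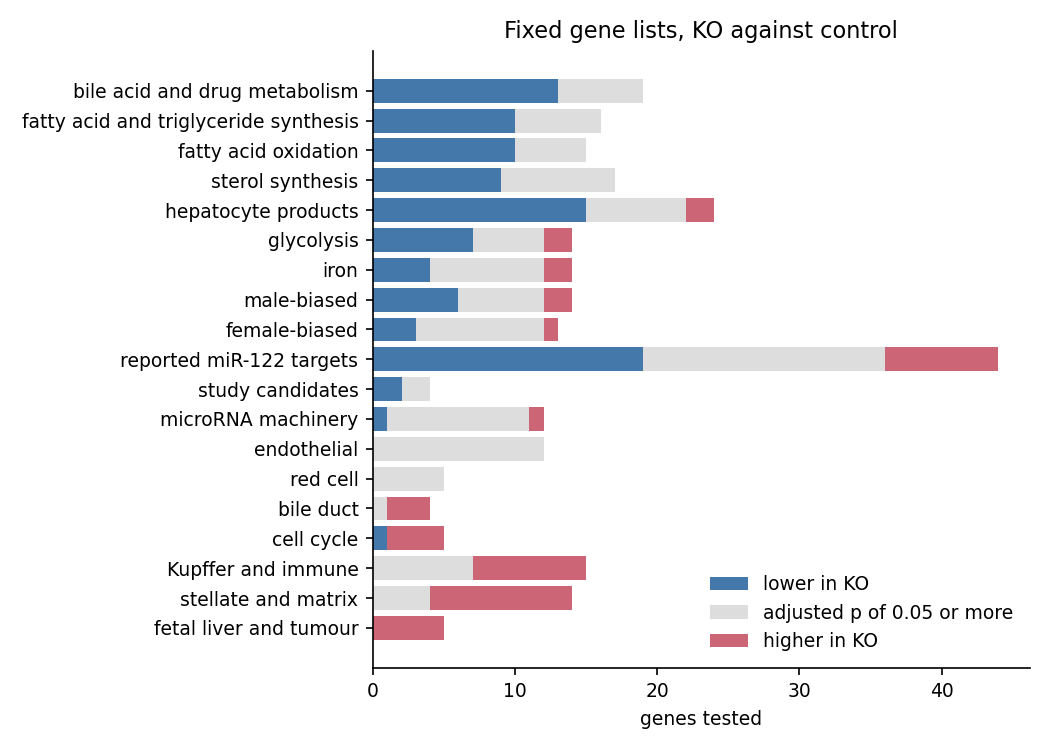
Number of tested genes of each fixed list that were lower in KO, higher in KO, or had an adjusted p of 0.05 or more. Of bile acid genes 13 of 19 were lower, and of matrix genes 10 of 14 were higher.

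Sex-biased liver genes were in part lower in KO of either bias. Of 14 male-biased genes 6 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.140; adjusted p = 0.299 with an estimated correlation), including Cyp4a12a (log2 -2.51), Cyp4a12b (-2.64), Mup21 (-2.19) and Slco1a1. In male libraries alone, an alternative added after the data were seen, the list stood lower by camera (adjusted p = 0.00307; adjusted p = 0.366 with an estimated correlation). Of 13 female-biased genes 3 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.779). Cyp2c69 (-2.73), Fmo2 (-2.22) and Sult2a1 (-2.62) fell, and A1bg rose (2.40), a value that rests on the 1 female KO library at 250.4 CPM. Without the sex term Cyp4a12a (adjusted p = 0.142), Cyp4a12b (0.111) and A1bg (0.96, adjusted p = 0.506) did not pass. Sult2a1 did not pass by limma-voom (adjusted p = 0.162), nor without control replicate 2 (adjusted p = 0.0631), control replicate 5 (0.0972), KO replicate 2 (0.0585) or KO replicate 3 (0.0621), or with the neuron-marker covariate (0.425). Cyp, Mup and Sult genes have near copies, so their assignment is uncertain.

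Between the sexes, Y-linked genes and 1 region of Xist, the RNA that silences an X chromosome in females, set the libraries apart as labelled. Xist summed over its regions did not, since male KO replicate 4 (359 CPM) was close to the female mean. Summed over genes, Eif2s3y had no read in 4 females and 31.6 ± 12.9 CPM in 5 males (SD), at least 34.7-fold higher against a floor of 3 counts over the females, Uty 0.248 ± 0.497 and 35.4 ± 18.4 CPM and Ddx3y 20.2 ± 10.8 and 186 ± 114 CPM (log2 3.10, adjusted p = 0.0250). Xist was at 385 ± 51.9 CPM in females and 130 ± 135 CPM in males (-2.36, adjusted p = 0.390). It passed by DESeq2 (-2.43, adjusted p = 0.0182), without KO replicate 4 (-2.77, adjusted p = 0.000445), in control libraries alone (-3.36, adjusted p = 0.000420) and with the neuron-marker covariate (-2.86, adjusted p = 0.000446). Male KO replicates 2 to 4 held 91.6, 126.1 and 359 CPM of it, and the male controls 11.96 and 63.1. The male KO levels had the order of the summed neuron markers (1590, 1970 and 6010 CPM). Whether both came from the same source was not tested. One region of Xist, overlapping its antisense partner Tsix (chromosome X, 103482392 to 103482461), differed more clearly (102 ± 28.4 against 2.71 ± 3.21 CPM, -5.50). Regions of Cyp3a41b (-5.30), Cyp2b13 (-4.75), A1bg (-4.28) and Slc22a26 (-3.70) were also higher in females, and those of Ddx3y (0.248 ± 0.497 against 60.6 ± 42.5 CPM), Uty (no read in females, at least 20.4-fold) and the urinary protein genes Mup7 (4.38), Mup15 (4.01) and Mup20 (3.32) in males. In all, 108 regions differed, 21 higher in females and 87 in males, and 36 genes (10 and 26). The count of regions was 40, 37, 32, 46 and 24 without controls 1 to 5 in turn, 226 without KO replicate 4, 6 with the replicate number as a block and 0 without a genotype term. A1bg did not pass without control 4 (adjusted p = 0.0593) or 5 (0.0633), Slc22a26 without control 4 (0.226), control 5 (0.281) or KO replicate 3 (0.0610), the Uty region without KO replicate 1 (0.0626), and Mup20 without control 1 (0.0553) or 5 (0.205). The Ddx3y gene did not pass without any 1 control (0.0508 to 0.128) or KO replicate 1 (0.0753).

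Whether the effect of genotype differed by sex rested on the single female KO library. No region passed by edgeR (0 of 17182, with 1246 at an unadjusted p under 0.05), 1 passed by DESeq2, and 3 passed without KO replicate 4. The fall of miR-122 7mer and 8mer regions, relative to regions without a site, had a median log2 difference of -0.41, males minus females. With 1 female KO library this cannot be told from a difference of that mouse.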

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

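The tests of H19 and of the miR-148 family without H19 were chosen only after their results were seen, as were the neuron, oligodendrocyte, astrocyte and other marker lists; the tests of brain RNA, of closure and of H19 regions over all families were written before they were run. Single libraries that stood apart were found by Dixon's test, which chance alone makes point to about 1 in 20 groups; it did so for 43 of 336.

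Transcripts of brain type were present in all 4 KO libraries and most abundant in replicate 4. Beyond the 23 neuron markers at 52.1 ± 2.89 CPM in controls and 1426, 1590, 1970 and 6010 CPM in KO replicates 1 to 4, Syt1 held 262, 287, 340 and 608 counts and Map2 155, 216, 291 and 481. All 17 neuron markers tested rose (camera adjusted p = 1.1e-11; adjusted p = 0.173 with an estimated correlation), and control liver held 2 of the 23 at 5 CPM or more. Markers nearly absent from control liver passed the filter only through the KO libraries, so that they rose was fixed in advance. The 318 genes silent in control liver, scaled by the neuron markers, varied between KO libraries by a coefficient of only 0.0760 (bootstrap 0.0415 to 0.108). For 1164 liver-expressed genes that rose it was 0.248 (0.233 to 0.263). The low spread may come from 1 source of brain RNA mixed into the KO libraries in different amounts. It went against the prediction for activation in separate mice, which was a spread like that of other genes. Activation of these genes together, to a different degree in each mouse, would keep the same proportions, so it is not excluded. How brain RNA, if mixed in, entered these libraries stays open.

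H19, an imprinted RNA of fetal liver, stood at 1537 ± 1735 CPM in controls (n = 5) and 33785 ± 4420.3 CPM in KO (n = 4), with control replicate 5 at 4476 CPM. Brain RNA would have put KO replicate 4 above the others by the ratio of the neuron markers, 3.62, but its ratio was 0.938. KO reads carried into control replicate 5 would have needed a neuron-marker excess of 10.9% of the KO level, and 0.193% was seen. The ratio of 0.938 argued against brain RNA as the main source of H19 in KO. The small neuron-marker excess argued against KO reads carried over together with the neuron markers. It cannot bear on KO liver RNA carried over without brain RNA, so carry-over stays open. Control replicate 5 was also the highest control at Igf2 (226 CPM, next 67.3). Renewed expression of a fetal gene in hepatocytes could be another explanation and was not tested.

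Of 16 other microRNA families, 7 took a higher share of counts in KO. With H19 regions left out 6 of the 7 stayed higher, so H19 alone was excluded, although for the miR-148 family the ratio dropped to 0.853 and H19 may account for it. Outside miR-122 regions only 2 of the 7 stayed higher, so closure of the shares after the loss of miR-122 reads could account for most of them. These 2 were the miR-148 family (ratio 1.25), for which H19 may account, and miR-23 (1.21). On the same measure the miR-15/16 family, not among the 7, was lower in KO (ratio 0.849, adjusted exact p = 0.0450). Among regions with a control mean of at least 1 CPM, 14 of 14 families stayed up by camera, as did 14 with the neuron-marker covariate. The first leaves in genes shared by brain and liver, and the second nearly coincides with genotype. Both also set the families against a background that held the miR-122 regions, whose fall alone can put other families higher. Neither test can therefore tell whether brain RNA contributed, which stays open. The 14 became 0 with an estimated correlation, and among regions without a miR-122 site only 1 of the 16 passed, lower.

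Of the other marker lists, oligodendrocyte genes rose (3 of 3 tested; camera adjusted p = 0.00629; adjusted p = 0.173 with an estimated correlation; 6 with a region, 2 of them at 5 CPM or more in control liver), with a replicate 4 ratio of 2.10. Of 5 astrocyte genes tested 3 rose and 1 fell (camera adjusted p = 0.0562; 7 with a region, 3 at 5 CPM or more), with a ratio of 1.89. Oligodendrocyte and astrocyte genes nearly absent from control liver could likewise be tested only where the KO libraries held reads. Skeletal muscle genes (7 with a region, 5 at 5 CPM or more) summed to 106.5 ± 103.6 CPM in controls and 40.9 ± 40.7 CPM in KO, and the 1 tested did not pass. Heart muscle genes (2 with a region), pancreas genes (1) and brain microRNA genes (3) gave 0 tested, and kidney and lung genes had no region.

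KO replicate 4 gave 20 of the values that stood apart, most of them at neuronal genes. It was highest, with the next KO library in parentheses, at the regions of Aldoc (266 CPM; 75.7), Syn1 (227; 62.4), Cadm2 (219; 68.2), Nap1l5 (188; 57.5) and Meg3 (1336; 436). Summed over genes it was highest at Rbfox1 (1194; 351), Cadm2 (609.0; 193), Csmd1 (472; 149), Dlgap1 (452; 121), Vsnl1 (431; 128), Tmem178b (418; 123), Slc24a2 (364; 99.9), Meg3 (8222; 2294), Peg3 (511; 192) and Pfkp (153; 71.0). It was lowest at Stab1 (11.4; 32.7), Col1a2 (217; 291), in pseudogenes (1.07% of counts; 1.42%) and in regions of miR-194 (2.16%; 2.69%) and miR-29 (4.07%; 5.63%).

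KO replicate 1, the only female of its group, was highest at Cyp2c69 (33.8 CPM; next 7.80), the A1bg gene (250.4; 23.4), Sult2a1 (18.9; 2.80) and regions of Xist (142; 8.16), Cyp3a41b (42.7; 1.95), Cyp2b13 (13.9; 1.95) and A1bg (11.9; 1.95). Control replicate 5 was highest at Igf2 (226; 67.3), Pfkp (9.40; 5.13) and the Tmed3 region (149; 76.9) and lowest in miR-30 regions (5.51%; 6.20%). Control replicate 2 was lowest at the Diap2 region (20.2; 43.0) and Pcna (13.5; 23.1), and highest at Sult2a1 (155; 32.2), deep intergenic sequence (2.13%; 1.90%) and pseudogenes (2.11%; 1.91%). Control replicate 1 was highest at Drosha (107.1; 83.0) and the Slc52a2 gene (43.7; 26.5), and control replicate 4 in miR-23 regions (2.06%; 2.01%). KO replicate 2 was highest at Apoc3 (345; 269), and KO replicate 3 was lowest at Scd1 (142; 198) and highest at the Mup20 region (976; 194) and the Slc52a2 region (1.87; 0). The fall of miR-122 regions relative to regions without a site had a median log2 difference of -0.41, males minus females. The female KO arm was 1 library, so this cannot be told from a difference of that mouse.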

How the results depend on the processing

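Alternatives chosen only after the data were seen were the neuron-marker covariate, control or male libraries alone, rows with a control mean of at least 1 CPM and regions without a miR-122 site. Regions called between KO and control, 7752, became 21743 with no filter, 3904 with the stricter filter, 2638 over 3' UTR rows, 4926 with the neuron-marker covariate and 5274 with replicate number as a block; leaving out 1 library gave 5205 to 9699, the latter without KO replicate 4. Replicate numbers did not pair (r from -0.089 to 0.001). Genes called, 3996, became 2624 with the block, 2067 over 3' UTR rows and 3095 to 4496 with 1 library left out. Sc5d turned to 0.14 over 3' UTR rows. The median miR-122 difference, -4.31, lay from -4.52 to -4.19 with 1 library left out, and over all settings from -4.95 (8mer sites) to -3.99 (block). For sex, 108 regions became 168 (DESeq2), 163 (limma-voom), 269 (no filter), 6 (block), 25 (3' UTR rows), 177 (neuron-marker covariate), 0 (no genotype term) and 338 (controls only), and 40, 37, 32, 46 and 24 without controls 1 to 5, or 226 without KO replicate 4. Other families past the threshold, 14, became 0 with an estimated correlation and 1 in regions without a miR-122 site. Gene lists, 8, became 0 with an estimated correlation, 15 by fry and 7 to 9 with 1 library left out. Annotation classes, 9, became 0 within sex, 0 without any 1 control, 8 over filtered rows, 10 without KO replicate 1 and 7 without each other KO replicate. For the interaction, 0 regions became 1 (DESeq2), 28 (no filter) and 3 (without KO replicate 4), with 0 when control replicate 1 was left out. The median change in log2 over rows shared with the main fit was 0.21 (library size), 0.23 (upper quartile) and -0.30 (3' UTR rows) for regions. For genes it was -0.32 (TMM without miR-122 rows), -0.25 (3' UTR rows) and 0.12 (library size). Of 132 named results, 2670 values stayed the same, 89 were weaker (26 with the neuron-marker covariate, 19 with the block), 13 stronger and 1 reversed.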

Other observations

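The splits of the libraries at random were chosen only after the results were seen; the test of target genes was written before it was run.

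For KO against control, 1 of 100 splits, the real one, called 7752 regions, and the highest other called 3505. For genes 1 of 100, the real one, reached 3996, and the highest other 1904. Both of these others set controls 1, 3, 4 and 5 against the rest, which is close to the real split. The groups thus differed more than random splits did, but the splits cannot tell genotype from brain-type RNA, present in all 4 KO libraries. For sex, 12 of 100 splits, the real one among them, called at least the real 108, so that count cannot be told from those of other splits. The highest, 669, set control replicate 2 and KO replicates 1 to 3 against the rest. This points to structure among the samples, with KO replicate 4 apart from the other KO libraries. Splits with such structure do not measure chance alone. They bear on the count of regions, not on Y-linked genes such as Eif2s3y, with no read in females and 31.6 CPM in males.

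AGO freed from miR-122 sites might bind more at other sites of the same genes. The 3' UTR regions without a site had a median log2 of 0.32 in 269 genes with a miR-122 3' UTR site and 0.64 in 1267 without. Against level-matched genes the difference was -0.0227 (permutation p = 0.592; central 95% of permuted values -0.100 to 0.0984). A gain was predicted to give a higher median with a permutation p under 0.05, and no gain a difference at or under 0. The median thus showed no gain, but the test cannot tell a gain inside the permuted range from none.

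Of 62 regions annotated as microRNAs, a group chosen after its values were seen, 18 rose, 1, over Mir122, fell and the others did not pass. In the imprinted cluster of chromosome 12 (109585796 to 109743811) 14 of 14 rose, at a median log2 of 5.12 with control levels near the floor, as for Mir379 (1.05 ± 1.16 against 88.9 ± 41.6 CPM, n = 5 and 4). The ratio of KO replicate 4 to the others was 1.01 there, unlike the neuron markers. Regions of the cluster passed the filter through the KO libraries, so that all of those tested rose was fixed in advance. Mir141 (log2 2.22), Mir200c (2.01) and Mir182 (2.18) rose as well.

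Repeats with a miR-122 match lost their reads as other sites did. In LTR repeats 52 of 52 regions with an 8mer and 73 of 73 with a 7mer fell, and they held 23.3% and 14.2% of control LTR counts. Of LTR regions without a site 4 fell and 19 rose.

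Regions with the "-B" class of miR-122 match fell (546 of 620; median log2 -3.63; camera adjusted p = 0.00493 with an estimated correlation). Around the Mir122 locus, regions upstream at 65246738 to 65246807 fell (286 ± 116 against 19.9 ± 6.51 CPM, TMM-scaled; log2 -3.69), whereas 65246489 to 65246558 rose (15.1 ± 5.999 against 88.5 ± 31.7 CPM; 2.86). Of the other flanking regions, those starting at 65250824 (-3.82) and 65246816 (-1.23) fell and those starting at 65247319 (2.51) and 65246016 (1.34) rose.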
